A study of Homo sapiens with 2 samples.

How the data were processed

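Gene expression was measured by RNA sequencing in HN6 cells, with 1 control library and 1 library of cells transfected with a ZNF582 plasmid. Per the labels' protocols, libraries came from total RNA prepared with the VAHTS Universal V6 kit, and whether the kit was used in a stranded form is not given in the sources used here. The labels do not say whether control cells received an empty vector. Per the submitters' processing notes, HISAT2 2.0.4 and StringTie 1.3.0 were used with the GRCh38 build. The counting program, the annotation release and any filter are not given in the sources used here.

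Per the file headers, the authors deposited 1 table with a count and an FPKM value per gene in each library, a log2 fold change, a p-value, a q-value and a call of up or down. Because the counting program is not stated, the deposited counts are treated as estimated counts, although they are whole numbers in every record. 1 record was broken over 2 lines and was rejoined before use. The lowest sum of both counts of a listed gene was 2. The deposited FPKM values were scaled by total counts alone, since the count ratio divided by the FPKM ratio was 1.205, the ratio of the column totals, in the 8848 genes with more than 200 counts in each library. The finite deposited log2 fold changes equalled the log2 ratio of FPKM without a pseudocount. The authors' calls had a q-value under 0.05 and a log2 fold change of 1 or more in size, as tested on the table. The spread that the authors assumed for the deposited p-value with 1 library per group is not given in the sources used here, so these p-values and q-values are not printed.

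Counts were scaled by total counts with TMM factors (1.04 for control and 0.962 for the ZNF582 library) from edgeR 4.0.16 in R 4.3.3. Genes with at least 20 counts in both libraries together were examined, which left 16669 of 25534. A gene was called higher or lower when its fold was 2 or more and the exact 95% Clopper-Pearson counting interval of the fold, conditional on the sum of both counts, excluded 1. No p-value was computed, since 1 library per group gives no replicate spread. The data hold no molecular identifiers, so reads are not independent molecules and intervals and floors cover counting error only. Where a library had 0 counts, the fold was taken against a floor of 3 counts in that library and is a lower bound. Divided by total counts without TMM factors, the floor equals 0.203 CPM in the control library and 0.169 CPM in the ZNF582 library. The printed folds against the floor use the TMM factors.

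For each of 32 fixed gene lists the median log2 fold of members with at least 20 counts was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list stands apart below percentile 2.5 or above percentile 97.5. This describes these 2 libraries and is not a test of the condition. The lists cover epithelial and desmosomal adhesion, EMT, keratinocyte differentiation, basal squamous cells, cell cycle phases, p53, apoptosis, interferon, antigen presentation, cytokines, hypoxia, stress responses, lipid synthesis, NRF2, signalling targets, matrix proteases, the KRAB corepressor complex, zinc finger genes near ZNF582, other cell types, ribosomal proteins, mitochondria, histones and housekeeping genes.

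The genes named were chosen by a rule fixed before the data were examined. It took ZNF582. It took the 12 highest and 12 lowest genes with a symbol by the interval bound nearest to no change, among genes past the 2-fold rule with at least 100 counts, leaving out ribosomal RNA, mitochondrial, immunoglobulin and T cell receptor genes. It took up to 4 members with the largest log2 fold, with at least 100 counts, from each list that stood apart or had 3 or more members past the rule, and 1 such member of other lists if past the rule. It took all measured zinc finger neighbours, and the 6 genes with the largest FPKM gain and the 6 with the largest loss. Other members are named where a list had few genes past the rule, or to show members that differed from their list. A few genes that the rule took are not reported here.

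Gene symbols and spans were compared with GENCODE 29 on GRCh38. Of the listed identifiers 25271 were found there, 23892 with the same span, and types, strands and exons were taken from it. Because strand use in counting is not stated, exonic overlap with another listed gene on either strand was marked for each gene. It applied to 35.4% of listed genes, 39.5% of those examined, 39.2% of the higher genes and 33.0% of the lower genes. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

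The procedure was tested on simulated counts with the means and depths of the 2 libraries over 16669 genes. Of 50 genes changed by each size, the rule called 47 at 2.5-fold, 49 at 4-fold, 50 at 8-fold and 1 at 1.5-fold. Of 16469 unchanged genes 67 were called, and 95.7% of intervals held the simulated fold. Simulated counts carried counting error alone, so these figures do not describe differences between cultures.

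Alternatives planned before the data were examined were total counts, median-of-ratios size factors, deposited FPKM with a pseudocount of 1 or 0.1, the log2 fold changes of the authors' deposited table, no minimum count or a minimum of 100, protein-coding genes only, 1.5-fold and 4-fold rules, no interval rule, and random lists without matching. Alternatives added after seeing the data left out genes with exonic overlap, matched random lists on expression and GC content, or drew random lists only from genes to which the table assigns a KEGG pathway. The annotations of the table other than KEGG pathways were not used here.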

Results

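RNA sequencing was performed on HN6, an established human line of tongue squamous cell carcinoma, to ask how the zinc finger protein ZNF582 affects gene expression in head and neck squamous cell carcinoma. There were 2 libraries, 1 from control cells labelled wild type and 1 from cells that overexpressed ZNF582 from a transfected plasmid. The control library held 14765244 assigned counts and the ZNF582 library 17792172. Of 25534 listed genes, 24095 had a count above 0 in the control library and 24519 in the ZNF582 library. Because each group had 1 library, no difference below has a replicate check, and none was tested against the spread between cultures. All intervals are 95% intervals that cover counting error only.

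ZNF582, a KRAB-type zinc finger protein of the class that recruits transcriptional corepressors, was far higher in the overexpressing cells. The gene (ENSG00000018869) lies on the minus strand of chromosome 19 from 56375846 to 56393545 in GRCh38. It had 14 counts in the control library and 277387 in the ZNF582 library, or 0.12 against 1974 FPKM. The log2 fold was 14.12 (interval 13.37 to 14.99), a ratio of 17777. ZNF582 alone took 1.56% of all counts in its library. The levels match the labels of both libraries.

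Among 16669 genes with at least 20 counts in both libraries together, 709 were at least 2-fold higher and 836 at least 2-fold lower in the ZNF582 library with an interval excluding 1. These 1545 genes were 9.3% of those examined, and 45.9% of them were higher. Past 4-fold, 187 genes were higher and 131 lower. The median log2 fold of all examined genes was -0.007, with quartiles at -0.33 and 0.31. The split depended on the scaling. Without TMM factors the median moved to -0.12, and 565 genes were higher against 1097 lower, so that 34.0% were higher. From the log2 fold changes in the authors' deposited table, at 1 or more in size and without the interval rule, 650 were higher and 1212 lower, or 34.9% higher. The authors' deposited table called 524 genes up and 692 down. Of the genes called in the authors' deposited table, 463 of those up were also higher by the 2-fold rule, 540 of those down were also lower, and 0 had the opposite direction.

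**Figure D1:**
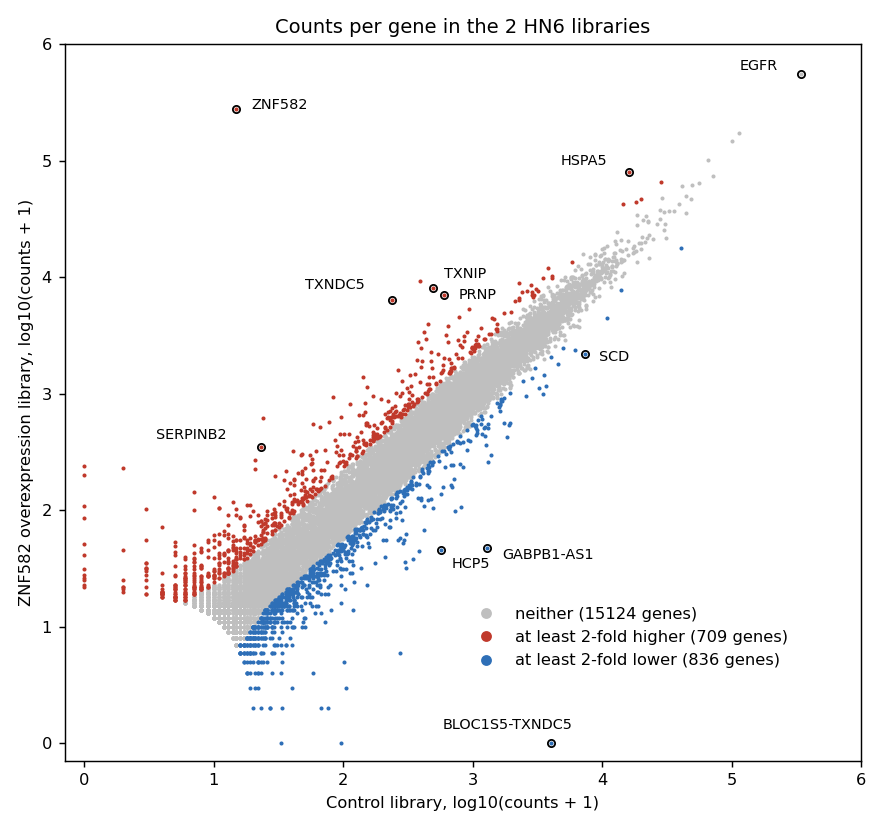
Counts per gene in the control library (horizontal axis, log10 of counts plus 1) and the ZNF582 overexpression library (vertical axis, same scale), 1 point per gene for the 16669 genes examined. Red points are the 709 genes at least 2-fold higher, blue points the 836 at least 2-fold lower and grey points the others, and ZNF582 lies far above the rest with 277387 counts against 14.

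The strongest single-gene differences upward after ZNF582 included TXNIP. This gene, which encodes a thioredoxin-binding inhibitor of glucose uptake, was 14.4-fold higher (13.2 to 15.8), and its relative ARRDC4 8.84-fold higher (7.43 to 10.6). PRNP, the prion protein gene, was 10.4-fold higher (9.52 to 11.3). BASP1, a membrane-bound signalling protein, was 12.1-fold higher (7.66 to 20.1), and VXN 21.1-fold higher (9.45 to 58.4). SERPINB2, the inhibitor of plasminogen activators also called PAI-2, was 14.3-fold higher (9.28 to 23.1), and the zinc finger gene ZNF551 10.3-fold higher (8.2 to 13.1). The last pair each had exonic overlap with another listed gene, which makes their counts uncertain.

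Among the strongest differences downward, ZBTB25, a BTB-domain zinc finger gene, was 10.4-fold lower in the ZNF582 library, and the zinc finger gene ZFP1 9.68-fold lower. NKRF, a repressor of NF-kB target genes, was 8.51-fold lower with 106 counts against 809, and MBNL3, a muscleblind-type RNA-binding protein, 10.9-fold lower. FBXO34, an F-box protein gene, was 8.31-fold lower. DTX4, a ubiquitin ligase gene of the Deltex family linked to Notch signalling, was 9.49-fold lower with 35 counts against 298. Noncoding transcripts were also among the lowest. GABPB1-AS1, annotated antisense to a transcription factor gene, was 31.5-fold lower, and HCP5 in the major histocompatibility region 14-fold lower. TGFB2-OT1 was 28.1-fold lower (10.7 to 105), on 4 counts against 101. It lies within the span of TGFB2 on the same strand. TGFB2 went the other way, at 330 counts against 151, or 1.96-fold higher (1.61 to 2.39), so reads may have been divided differently between them. ZBTB25, NKRF, FBXO34, GABPB1-AS1, HCP5 and TGFB2-OT1 had exonic overlap with other listed genes, so their counts are uncertain too.

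Several of the largest ratios belonged to genes that share exons with a readthrough neighbour or have near copies, and are uncertain for that reason. TXNDC5, a protein disulfide isomerase of the endoplasmic reticulum on chromosome 6 (7881517 to 7910814, minus strand), was 24.2-fold higher, with 6357 counts against 236. BLOC1S5-TXNDC5, a readthrough gene across the same exons (7881522 to 8064364), had 0 counts in the ZNF582 library against 4011 and was at least 1490-fold lower against the floor of 3 counts, with a counting interval that starts at 1211. Summed, the counts of TXNDC5 and BLOC1S5-TXNDC5 were 6357 against 4247, a ratio of 1.34 after scaling. PPAN-P2RY11, a readthrough gene, had 200 counts against 0 and was at least 59.8-fold higher against the same floor, with an interval that starts at 48.2. RAB4B-EGLN2, also a readthrough gene, was 10.1-fold lower. TMEFF1, which shares exons with MSANTD3-TMEFF1, had 2 counts against 105, a ratio of 58.5 (15.8 to 490). The ribosomal protein pseudogene RPS26P19 had 227 counts against 1, a ratio of 204 (36.2 to 8079).

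In absolute terms, the largest FPKM gains besides ZNF582 were in small structural RNAs. RN7SL2 and RN7SL1, the RNA of the signal recognition particle that directs proteins to the endoplasmic reticulum, reached 27362 and 18869 FPKM against 22623 and 14808. RN7SL3 stood at 2798 against 1835, AL162581.1 at 8099 against 5875, and RMRP, the RNA of an RNase complex that processes ribosomal RNA, at 7251 against 4750. None of these 5 reached 2-fold, and the 7SL copies share nearly all of their sequence. The largest FPKM losses were in H1-5, PRDX1, H3C1, H2AC17, RPL21P75 and H4C4. Of these, PRDX1, a peroxiredoxin that removes peroxides, was 2.03-fold lower, and the histone gene H3C1 2.28-fold lower. The others did not pass 2-fold with TMM factors, which FPKM lacks. H1-5 was 1.99-fold, H2AC17 1.46-fold and H4C4 1.33-fold lower, and RPL21P75, at 1.08-fold lower, was nearly unchanged. RN7SL1, RMRP, PRDX1, H2AC17 and RPL21P75 had exonic overlap with another gene, and histone genes and RPL21P75 have near copies.

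The 32 gene lists were fixed before the data were examined. Of these, 17 had a median outside the central 95% of 10000 random lists matched on mean expression. There were 8 above and 9 below, where 1.6 in all are expected for lists of unrelated genes. Members of a list can vary together between any 2 cultures and some lists share genes, so the excess does not measure an effect of ZNF582. Where 5 or fewer members of a list passed the 2-fold rule all or most are named below, and those outside the rule for named genes were chosen after their values were seen. The 25 housekeeping controls had a median of -0.15 (percentile 0.5), with 0 members past 2-fold. PGK1 at -0.62, with exonic overlap, was the farthest below 0. With random lists not matched on expression their percentile was 10.3. The 48 cytosolic ribosomal proteins had a median of 0.01 (percentile 25.7), also with 0 past 2-fold. Small medians of other lists can be read against these control lists.

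**Figure D2:**
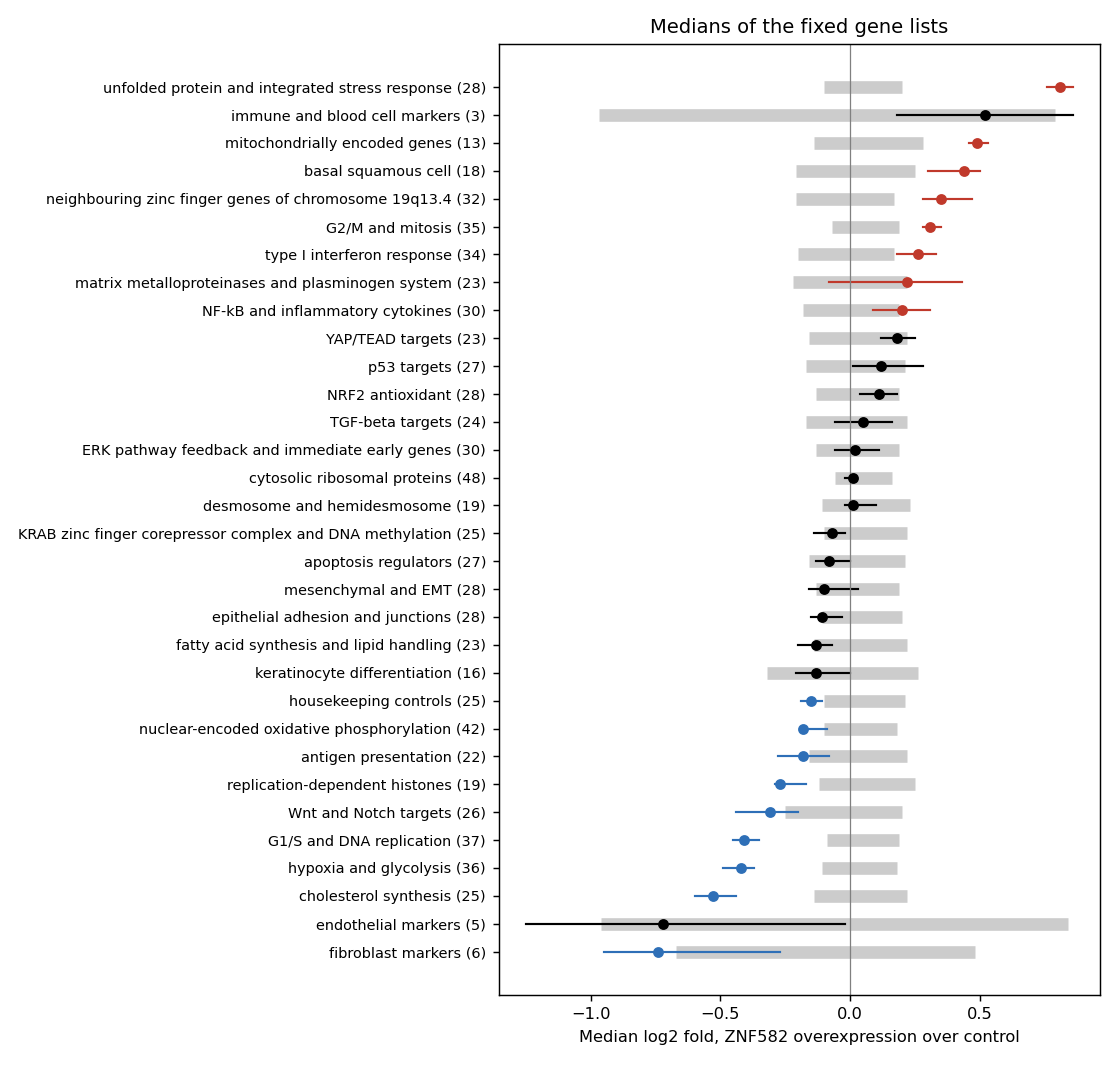
Median log2 fold (ZNF582 overexpression over control) of each of the 32 gene lists, with the number of measured members in parentheses. Points are medians, thin bars their 95% counting intervals, grey bars the central 95% of 10000 expression-matched random lists, red lists lie above and blue lists below that range, and the stress response list has the highest median at 0.81.

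Genes of the unfolded protein and integrated stress response were higher as a group in the ZNF582 library. The 28 measured members had a median log2 fold of 0.81 (0.76 to 0.86), at percentile 100, with 18 above 0 and 10 below 0. By the 2-fold rule 13 were higher, 2 lower and 13 neither. HSPA5, the main Hsp70 chaperone of the endoplasmic reticulum, was 4.45-fold higher (4.38 to 4.53), with 79546 counts against 16027. PPP1R15A, which directs dephosphorylation of eIF2-alpha, was 5.31-fold higher (4.89 to 5.79), the co-chaperone gene DNAJB9 4.31-fold higher (3.91 to 4.77) and the stress transcription factor gene ATF3 3.55-fold higher (3.09 to 4.09). DDIT3, which encodes CHOP, was 3.05-fold higher and TRIB3 2.56-fold higher. The others past the rule were the endoplasmic reticulum folding and quality control genes CRELD2, SDF2L1, HERPUD1, HSP90B1, DNAJC3, PDIA4 and MANF, from 2.49-fold down to 2.05-fold higher. Other members did not follow: ASNS stood at -0.14, PSAT1 at -0.83 and PHGDH at -0.62 on the log2 scale, and ATF4 itself at 0.08. CHAC1, a glutathione-degrading enzyme gene induced by ATF4, was 2.88-fold lower and the lipoprotein receptor gene VLDLR 3.14-fold lower. DNAJB9, DDIT3, HSP90B1, CRELD2 and VLDLR had exonic overlap with other listed genes.

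Cell cycle genes divided by phase. The 37 genes of G1/S and DNA replication had a median of -0.41 (-0.45 to -0.35), at percentile 0.0, and 33 of them lay below 0. Only MCM6, a subunit of the replicative helicase, passed 2-fold, at 2.20-fold lower (2.03 to 2.39). E2F2 (1.99-fold), the sliding clamp gene PCNA (1.90-fold) and E2F1 (1.86-fold) came next on the lower side without passing the rule. The 35 genes of G2/M and mitosis had a median of 0.31 (0.28 to 0.35), at percentile 100, with 30 above 0. AURKA, a kinase of spindle assembly, was 2.32-fold higher (2.18 to 2.46). BIRC5, which encodes survivin and belongs to the same list, was 3.05-fold lower (2.69 to 3.47). CDC25C, with exonic overlap, at 1.89-fold and CKAP2 at 1.63-fold higher did not pass 2-fold. Replication-dependent histones, which are made in S phase, had a median of -0.27 over 19 genes (percentile 0.0). Within this list H4C15 was the 1 gene past 2-fold, at 3.55-fold lower, and its copies and overlaps make it uncertain. H1-5 stood at 1.99-fold lower. The histone gene H3C1, outside this list, was 2.28-fold lower (2.09 to 2.49). With unmatched random lists the histone percentile was 2.8.

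The list of cholesterol synthesis and that of hypoxia and glycolysis were each lower as a group in the ZNF582 library. The 25 cholesterol synthesis genes had a median of -0.53 (-0.60 to -0.44), at percentile 0.0, and 23 of 25 lay below 0. Among those past 2-fold were INSIG1, a sterol-regulated retention factor of SREBP, at 2.43-fold lower (2.12 to 2.79), and the mevalonate pathway kinase gene PMVK at 2.09-fold lower. FDFT1, squalene synthase, was 1.74-fold lower, with exonic overlap. The 36 hypoxia and glycolysis genes had a median of -0.42 (-0.49 to -0.37), at percentile 0.0, with 31 below 0. CA9, a hypoxia-induced carbonic anhydrase, was 4.12-fold lower (2.64 to 6.62) and DDIT4, an inhibitor of mTORC1 signalling, 3.51-fold lower (3.29 to 3.75), both with exonic overlap. MXI1, a MYC antagonist of the same list, was 2.37-fold higher (2.04 to 2.76). The neuronal-type enolase gene ENO2, at 1.96-fold lower, did not pass. Fatty acid and lipid handling genes had a median of -0.13 (percentile 3.3, 23 genes) and did not stand apart. Within that list the desaturase gene SCD was 3.71-fold lower (3.54 to 3.90) and the triglyceride synthesis gene DGAT2 2.59-fold lower.

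Protein-coding genes of the mitochondrial genome were higher, and nuclear genes of oxidative phosphorylation lower as a group. All 13 protein-coding genes of the mitochondrial genome had a log2 fold above 0, with a median of 0.49 (0.46 to 0.53) at percentile 100. The highest were MT-ND3 at 1.77-fold, MT-CO2 at 1.52-fold, MT-ATP6 at 1.51-fold and MT-CO3 at 1.5-fold, and 0 passed 2-fold. The ribosomal RNA gene MT-RNR2 of the same genome, outside this list, was 6.77-fold lower on 13 counts against 79. These counts are far below those of MT-CO2, at 18411 against 10890. The ratio may depend on how ribosomal RNA was kept or counted and is not read as a difference in expression. Mitochondrial transcripts made up 0.906% of counts in the ZNF582 library and 0.713% in the control library. The 42 nuclear genes of oxidative phosphorylation had a median of -0.18 (percentile 0.1), again with 0 past 2-fold, NDUFB10 being 1.82-fold, ATP5MC2 1.5-fold, NDUFS5 1.47-fold and ATP5F1A 1.45-fold lower. MT-ATP6, MT-CO3, ATP5MC2 and ATP5F1A had exonic overlap. That median of -0.18 is close in size to the -0.15 of the housekeeping controls.

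**Figure D3:**
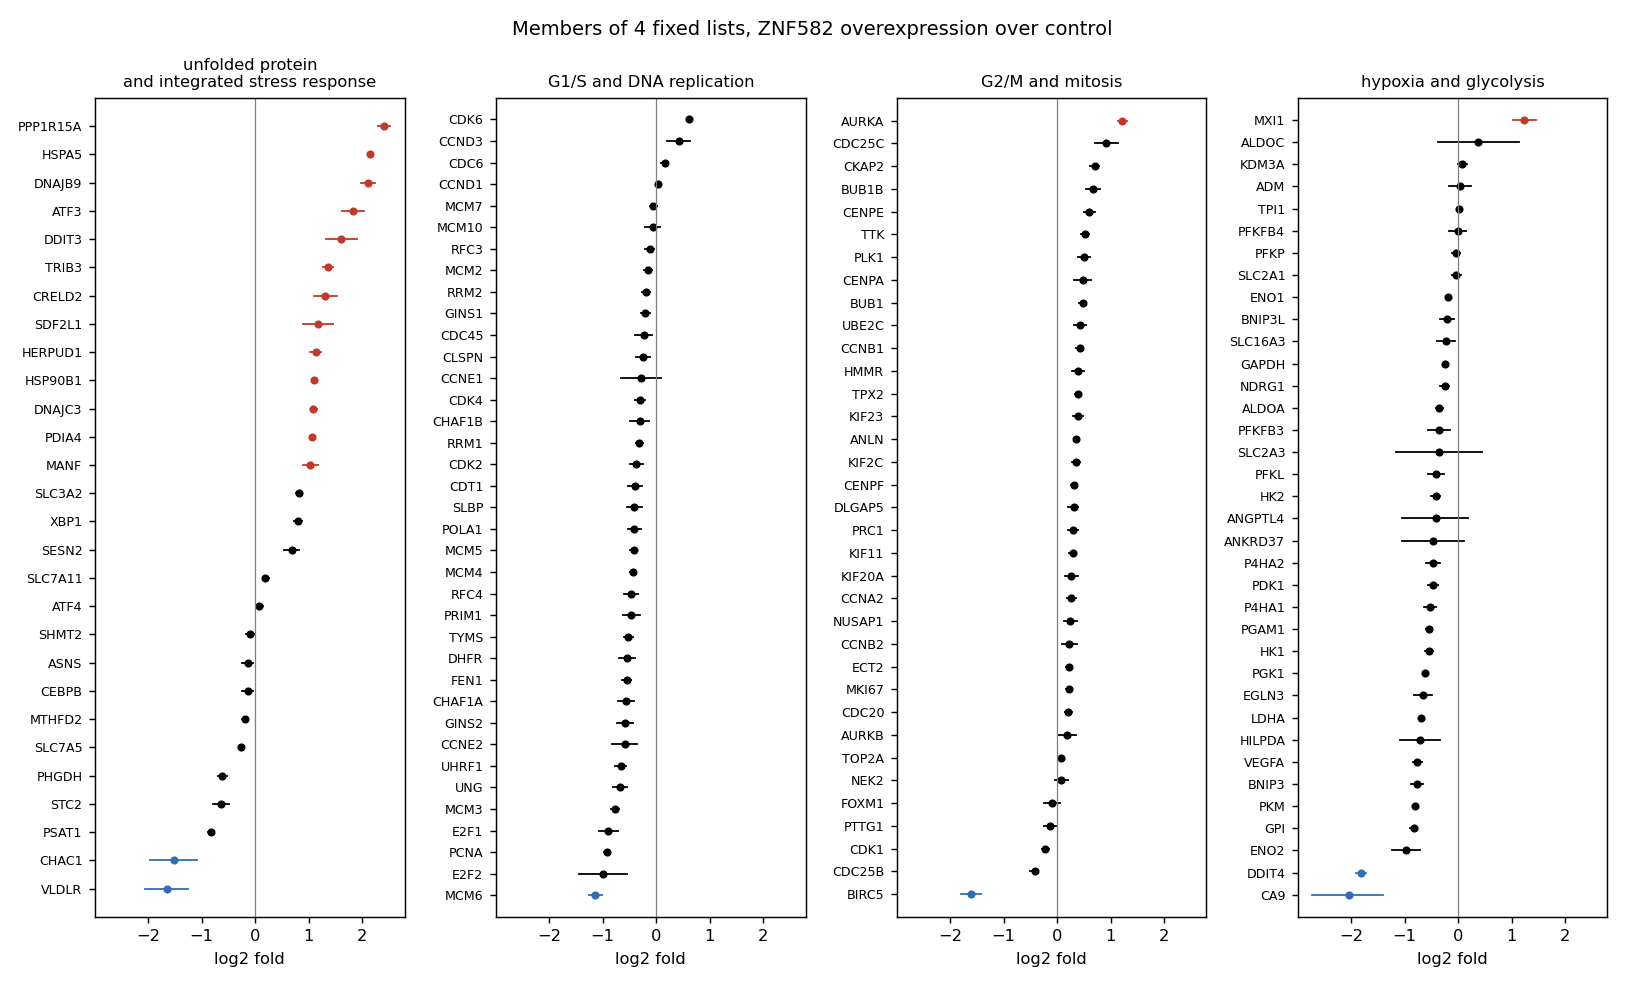
Log2 fold (horizontal axis, ZNF582 overexpression over control) of each measured member of 4 gene lists, with 95% counting intervals as bars. Red members passed the 2-fold rule upward and blue members downward, and 13 members of the stress response list are red while 33 of 37 members of the G1/S list lie below 0.

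The basal squamous cell list was higher as a group, whereas junction and differentiation lists did not stand apart with the main settings. The 18 measured genes of the basal squamous list had a median of 0.44 (0.30 to 0.50), at percentile 99.9, with 12 above 0 and 6 below 0. The stress-associated keratin gene KRT17 was 3.89-fold higher (3.56 to 4.24), KRT16 2.69-fold higher (1.88 to 3.93) and KRT6A 2.13-fold higher. On the lower side were KRT15, a keratin of basal cells, at 2.11-fold, and the protocadherin gene FAT2 at 2.45-fold. EGFR, the growth factor receptor that held 3.12% of counts in the ZNF582 library and 2.32% in the control library, was 1.46-fold higher and did not pass. Keratin genes have near-identical copies, and FAT2 and EGFR had exonic overlap, so these values are uncertain. KRT6A also had fewer than 100 counts in both libraries together. Epithelial adhesion and junction genes had a median of -0.11 (percentile 2.9, 28 genes), with the tight junction gene TJP3 past 2-fold at 6.13-fold lower on 4 counts against 22. The adhesion and junction list did stand apart, lower, with at least 100 counts (percentile 2.2) and from FPKM with a pseudocount of 0.1 (percentile 1.5). The nectins, adhesion receptors of adherens junctions, went both ways, with NECTIN1 at -0.85, NECTIN3 at -0.24, NECTIN4 at -0.02 and NECTIN2 at 0.27. Desmosome and hemidesmosome genes had a median of 0.01 (percentile 31.8, 19 genes), and LAMB3, a chain of laminin-332, was 2.62-fold higher (2.57 to 2.67). Keratinocyte differentiation genes had a median of -0.13 (percentile 23.1, 16 genes), with LCN2 2.21-fold higher and SPRR2D at 34 counts against 2, a ratio of 15.3 (3.91 to 131.0).

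Mesenchymal and matrix genes showed individual differences in both directions. The 28 mesenchymal and EMT genes had a median of -0.10 (percentile 4.8), with 5 past 2-fold higher and 1 lower. This list stood apart on the lower side from FPKM with a pseudocount of 1 (-0.28, percentile 0.3) or 0.1 (-0.31, percentile 0.2) and without genes that have exonic overlap (-0.20, percentile 2.1), and had a median of 0.02 (percentile 47.2) with at least 100 counts. SNAI2, which encodes the transcription factor Slug, was 3.05-fold higher (2.79 to 3.35), with 2025 counts against 595. ZEB1, another EMT transcription factor gene, was 2.91-fold higher (1.84 to 4.75) on 81 counts against 25. Its level was low in both libraries, at 0.23 against 0.085 FPKM. The collagen crosslinking enzyme gene LOX was 2.91-fold higher (2.08 to 4.14) on 149 counts against 46, and below 1 FPKM in both libraries. Tenascin C (TNC) was 2.62-fold and the activin subunit gene INHBA 2.53-fold higher. TWIST1 was 2.01-fold lower. VIM and CDH2, common mesenchymal markers, stood at 0.09 and 0.22, and CDH1 at -0.54. ZEB1, LOX, VIM, CDH2 and CDH1 had exonic overlap with other genes. The 23 genes of matrix metalloproteinases and the plasminogen system had a median of 0.22 at percentile 97.8, with an interval of -0.08 to 0.43 that includes 0. Besides SERPINB2, ADAMTS6 was 4.28-fold and ADAMTS1 2.61-fold higher. MMP28, with fewer than 100 counts in both libraries together, was 2.53-fold lower, and PLAT, tissue plasminogen activator, 1.80-fold lower without passing. The median of this list had the opposite sign from FPKM with a pseudocount of 1, at -0.12.

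Immune signalling genes differed in part. The 34 type I interferon response genes had a median of 0.26 (0.18 to 0.33), at percentile 99.7, with 4 higher and 0 lower by the 2-fold rule. These were the antiviral GTPase genes MX2 at 5.08-fold (2.92 to 9.48) and MX1 at 2.16-fold, the RNA sensor gene OAS2 at 2.29-fold and IFI27 at 2.07-fold, and IRF9 stood at 1.98-fold. MX1 and IRF9 had exonic overlap, and without such genes the interferon median was 0.15, at percentile 94.2, where the list no longer stood apart. From FPKM with a pseudocount of 1 it was -0.01, at percentile 83.2. The 30 NF-kB and inflammatory cytokine genes had a median of 0.20, at percentile 97.9, with 5 higher and 3 lower. IL24 was 10.05-fold higher (6.35 to 16.8), IL11 3.94-fold (3.49 to 4.46), IL6 3.29-fold (2.75 to 3.97), CXCL10 4.49-fold and CCL5 2.52-fold higher. TNFSF15 was 3.17-fold lower and CSF2 2.37-fold lower, and CCL28 had 3 counts against 57, a ratio of 21.2 (6.89 to 105.7). The cytokine list no longer stood apart without genes that have exonic overlap, which leaves out IL6 (percentile 91.1), with at least 100 counts (96.6) or from FPKM with a pseudocount of 1 (96.9). The 22 antigen presentation genes had a median of -0.18 at percentile 1.6. CD274, which encodes the checkpoint ligand PD-L1, was 3.20-fold lower (2.55 to 4.03), the class II transactivator gene CIITA 3.34-fold lower and HLA-DMB 2.04-fold lower, while ERAP2, PSMB10 and PDIA3 stood at -0.62, -0.50 and 0.54. The antigen presentation list no longer stood apart under 7 of 12 alternatives, at percentiles from 3.0 with at least 100 counts to 14.3 from FPKM with a pseudocount of 1. CIITA, PSMB10 and PDIA3 had exonic overlap. IFI27, CXCL10, CIITA and HLA-DMB each had fewer than 100 counts in both libraries together, so their ratios are less certain.

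Of the signalling lists, the Wnt and Notch targets stood apart and the others did not. Among 30 ERK feedback and immediate early genes (median 0.02, percentile 48.8), DUSP1, a phosphatase that inactivates MAP kinases, was 7.24-fold higher (6.54 to 8.03). FOSB was 3.22-fold and JUN 2.61-fold higher along with IL11, whereas the ERK feedback genes SPRY1, DUSP6 and ETV1 were 3.53-fold, 2.68-fold and 2.67-fold lower. Wnt and Notch target genes had a median of -0.31 at percentile 0.7 over 26 genes. The Wnt antagonist gene DKK1 was 3.46-fold higher (3.31 to 3.63) and HES4 2.78-fold higher, DTX4, HES2, LGR6 and SP5 were lower, and WNT7A stood at 1.98-fold lower. Against random lists from genes with a KEGG pathway the Wnt and Notch percentile was 5.9, so that the list no longer stood apart. TGF-beta targets had a median of 0.05 (percentile 61.8, 24 genes), with ID2 4.56-fold higher, SMAD6 5.02-fold lower and ID1 2.28-fold lower. YAP/TEAD targets had a median of 0.18 (percentile 94.4, 23 genes), with ANKRD1 4.11-fold higher (3.17 to 5.39), IGFBP3 2.75-fold and GADD45B 2.07-fold higher. The YAP/TEAD list stood apart, higher, without genes that have exonic overlap (percentile 99.0) and against random lists from genes with a KEGG pathway (97.7). DUSP6 and DKK1 had exonic overlap. HES2, LGR6, SP5, ID2, SMAD6 and IGFBP3 each had fewer than 100 counts in both libraries together, so their ratios are less certain.

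Stress outcome lists did not stand apart as groups. The 27 p53 targets had a median of 0.12 (percentile 87.4). GADD45A, a stress sensor that interacts with PCNA, was 5.20-fold higher (4.82 to 5.61) and its relative GADD45B 2.07-fold higher, whereas PMAIP1, which encodes the proapoptotic protein NOXA, was 2.42-fold lower and FDXR 2.11-fold lower. CDKN1A, the p21 gene, stood at 0.09. The 27 apoptosis regulators had a median of -0.08 (percentile 12.2). The BH3-only genes BMF and BCL2L11 were 5.82-fold (3.70 to 9.52) and 2.17-fold lower, and CFLAR, which encodes an inhibitor of caspase-8 activation, was 2.05-fold higher. BCL2L11 and CFLAR had exonic overlap, as did OSGIN1, UGDH and PRDX1 of the next list. The 28 NRF2 antioxidant genes had a median of 0.11 (percentile 86.9), with AKR1C1 2.98-fold, AKR1C2 2.82-fold, OSGIN1 2.21-fold, UGDH 2.15-fold and the thioredoxin reductase gene TXNRD1 2.10-fold higher, and PRDX1 lower. AKR1C1 and AKR1C2 are near-identical copies, and AKR1C2 had fewer than 100 counts in both libraries together.

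The zinc finger list from the region of chromosome 19q that holds ZNF582 was higher as a group. The 32 measured members of the neighbouring list had a median of 0.35 (0.28 to 0.47), at percentile 100, with 25 above 0. ZNF551, ZNF71 at 5.56-fold (2.83 to 12.2), ZNF550 at 2.46-fold, ZNF211 at 2.07-fold and ZNF416 at 2.06-fold were higher by the 2-fold rule, and ZNF329 was 3.37-fold lower (2.44 to 4.71). The others ranged from ZNF418 at -1.03, on 12 counts against 22, to ZNF304 at 1.0. Closest to ZNF582 among the measured members lay ZSCAN5A at 0.33, ZNF470 at -0.11 and ZNF71. The other measured members start at position 57191500 or beyond, so the median does not describe the immediate surroundings of ZNF582. Of the 32 genes, 17 had exonic overlap with another listed gene, ZNF551, ZNF550, ZNF304 and ZSCAN5A among them. The 25 genes of the KRAB zinc finger corepressor complex and DNA methylation had a median of -0.07 (percentile 5.8) with 0 past 2-fold, TRIM28, the corepressor itself, being at -0.40 and SETDB1, its histone methyltransferase partner, at 0.67 with exonic overlap. Without genes that have exonic overlap this list stood apart on the lower side (percentile 1.4).

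Markers of other cell types were scarce. Of 14 fibroblast markers 6 could be examined, with a median of -0.74 at percentile 1.5, and LUM at 4.01-fold, PDGFRB at 2.18-fold and ACTA2 at 2.06-fold were lower on 10, 49 and 13 counts in the ZNF582 library. COL1A1 at -0.14, TAGLN at 0.06 and FBLN1 at -0.43 were close to 0 or slightly below. ACTA2, TAGLN and CD68 had exonic overlap. The fibroblast list no longer stood apart under 6 of 12 alternatives, at percentiles from 2.5 to 27.6. Of 10 endothelial markers 5 could be examined (median -0.72, percentile 7.2), with VWF 2.87-fold higher on 16 counts against 5. Of 20 immune and blood cell markers 3 could be examined, CD68, CSF1R and ITGAM, with a median of 0.52 (percentile 92.6) and 0 past 2-fold.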

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

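Leaving out genes with exonic overlap and changing the pool or the GC content of random lists were chosen after the data had been seen. No paired analysis was possible because each group had 1 library. ZNF582 was higher throughout, with a log2 difference of 10.78 from FPKM with a pseudocount of 1 and 13.13 with 0.1, where the pseudocount shrinks the ratio by construction. The number of higher genes was 169 from FPKM with a pseudocount of 1, 422 with 0.1, 395 with at least 100 counts, 1650 at 1.5-fold, 187 at 4-fold and 431 without genes that have exonic overlap. The number of lower genes was 190 from FPKM with a pseudocount of 1, 352 with at least 100 counts, 1823 at 1.5-fold and 131 at 4-fold. Each of these settings changes the rule or the genes examined. Between 13 and 17 of the 32 lists stood apart under each alternative. The interferon median was -0.01 from FPKM with either pseudocount. The metalloproteinase and plasminogen median was -0.12 and -0.13 from FPKM with a pseudocount of 1 and 0.1, and -0.07 without genes that have exonic overlap. Lists that stood apart with the main settings and not under some alternatives were also the cytokine, antigen presentation, Wnt and Notch, fibroblast, histone and housekeeping lists. The metalloproteinase and plasminogen list was also within the central 95% without a minimum count (percentile 95.1) and with unmatched random lists (97.4). The opposite held for the adhesion and junction, mesenchymal, YAP/TEAD and KRAB corepressor lists, for the lipid handling list without a minimum count (percentile 2.4), and for the endothelial list with unmatched random lists (percentile 0.9). Medians from FPKM lack the TMM factors and cover genes with at least 1 FPKM in the higher library. Total counts alone moved the interferon median from 0.26 to 0.15 and the mesenchymal median from -0.10 to -0.22. Their percentiles stayed at 99.7 and 4.8, so this scaling lowers medians without changing which lists stand apart. The cause of the other changes and reversals was not tested. The stress response, G1/S, G2/M, cholesterol, hypoxia, basal squamous, zinc finger neighbour, mitochondrial and oxidative phosphorylation lists stood apart in the same direction under all alternatives run. Depth limits genes with few counts, as for ZNF418, whose 2.04-fold lower level on 12 counts against 22 had an interval that included 1.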

Other observations

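The tests of same-strand pairs and of other chromosomes, and the comparison of all KEGG pathways, were chosen after the result was seen. Among 285 KEGG pathways with 15 to 300 examined genes, 5 had medians above and 132 below the central 95% of expression-matched random lists. For pathways of unrelated genes 14.2 are expected outside, but pathways share genes and their members can vary together. The pathways above were ribosome biogenesis in eukaryotes (median 0.31, 79 genes), protein export (0.30, 22 genes), basal transcription factors (0.22, 42 genes), protein processing in the endoplasmic reticulum (0.21, 150 genes) and RNA transport (0.13). In ribosome biogenesis 1 gene was at least 2-fold higher, the mRNA export factor gene NXF1 at 2.19-fold, and 2 were lower, MT-RNR2 at 6.77-fold on 13 counts against 79 and RPP25 at 4.46-fold on 4 counts against 16. The MT-RNR2 ratio is again not read as a difference in expression. Nucleolar factors such as GNL2 at 1.72-fold, UTP15 at 1.63-fold and NOL6 at 1.61-fold higher did not pass 2-fold. RPP25, GNL2 and UTP15 had exonic overlap. Pathways below included terpenoid backbone biosynthesis (-0.34, 19 genes), which overlaps cholesterol synthesis, pyruvate metabolism (-0.29, 31 genes), glycolysis and gluconeogenesis (-0.28, 43 genes) and ECM-receptor interaction (-0.26, 51 genes). The choice of random genes mattered: the 4906 examined genes with a KEGG pathway had a median of -0.03 and the 11763 without one 0.01. With random lists drawn only from genes with a pathway, 11 pathways lay above and 57 below, and the 9 named here stood apart in the same direction.

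Zinc finger genes were higher as a group across the genome and not just in the region of chromosome 19q that holds ZNF582. The 423 examined genes with a ZNF symbol had a median log2 fold of 0.24 (percentile 100), with 66.9% above 0, 31 at least 2-fold higher and 16 lower. Those on chromosome 19, 197 genes, had a median of 0.28.

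Technical sources of the zinc finger pattern were weighed. Reads of the very abundant ZNF582 transcript assigned to similar genes would raise only genes resembling it, but the 360 zinc finger genes sharing no 25-base stretch with ZNF582 had a median of 0.23, above the upper end of the central 95% of random lists at 0.03. Matching random lists on GC content as well left the family at percentile 100. A change confined to chromosome 19 is argued against by the median of 0.2 on other chromosomes, where random lists reached 0.05. Whether the shift follows ZNF582 or a difference between cultures stays open with 1 library per group, and replicate cultures with an empty vector control would be needed to test it.

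The higher level of endoplasmic reticulum stress genes was also weighed. With random lists matched on GC content as well as expression the percentile was 100, which argues against GC bias. With 1 library per group, a difference in culture or transfection between the 2 libraries cannot be told apart from an effect of ZNF582 itself. The labels name no vector control that would separate ZNF582 activity from transfection itself or from making a very abundant plasmid-encoded protein.

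Opposite differences of genes that share exons, such as TXNDC5 and BLOC1S5-TXNDC5, were examined as a sign of reads divided differently between overlapping models. Among 3160 overlapping pairs of examined genes, 17 had opposite 2-fold differences, where the central 95% of 1000 random pairings reached 21. On the same strand there were 11 of 929 pairs, where random pairings gave 7.4 on average and the central 95% reached 13, against 5 pairs with the same direction, where random pairings gave 7.3. Only pairs in which both genes passed 2-fold were counted, so a redistribution that changes 1 partner little was not seen. In 13 of the 17 opposite pairs the summed counts differed by less than 2-fold, which opposite changes of separate genes can also give. Neither count of opposite pairs went beyond the central 95% of random pairings. The counts are small, with 95% counting intervals of 9.9 to 27.2 and 5.5 to 19.7 that extend past those limits, so a redistribution of reads stays open, also for single pairs such as TMEFF1 with MSANTD3-TMEFF1, whose summed counts had a ratio of 1.06.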
